A study of Mus musculus with 32 samples.

How the data were processed

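ATAC-seq libraries of LSK cells from C57BL/6 mice were used, 32 in all. Per the labels' protocols, nuclei were incubated with a Tn5 transposome and the products amplified with 10 PCR cycles. The submitters' processing notes name Trim Galore, MACS2, deepTools, DiffBind and HOMER and the genome build mm10. The aligner, the MACS2 settings, any shift of reads for the Tn5 offset, the removal of duplicates and the way regions were merged were not given in the sources used here, and each could change the measurements.

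Tests were two-sided. The deposited count tables hold raw counts per region, whole numbers whose sums differ between libraries, with no scaling. The table of the developmental series has 99037 regions of 501 to 2971 bp (median 551 bp) and 26 libraries. The table of the cultured cells has 147852 regions of 501 to 3152 bp (median 516 bp) and 6 cultured libraries. It also has 3 columns named as uncultured E12.5 FL libraries, which entered no comparison. All columns matched a sample by name. The deposited peak lists, called per library, give for each peak a display score, a fold enrichment ratio over the local background, and −log10 p and −log10 q, as the authors' caller wrote them. They were used to count, filter and overlap peaks. The fold enrichment only matched lists with count columns.

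Groups were taken from the sample titles. The library 8w BM 3 has the title of 8w BM and a stage label of E12.5, and its peak list correlated best with the column of its own name (r = 0.26). The labels do not say whether libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Libraries of a group differed by more than sampling noise (chi-square per region 2.11 to 5.88), so none was treated as a repeat deposit.

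Regions were kept with filterByExpr of edgeR (minimum count 10), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The 26 developmental libraries shared a fit with a mean for each of 9 groups, and the 6 cultured libraries were fitted alone. Fold changes are of the group named before the other. Levels are CPM scaled by TMM, and log2 CPM used a prior count of 2. Principal components used the 5000 most variable regions. Peak numbers were compared by an exact permutation test on log10 numbers, whose smallest p is 0.1 for 3 against 3 libraries and 0.2 for 3 against 2. Overlaps were made with bedtools 2.31.1 at 1 base, and tables of the developmental and cultured libraries were joined where regions overlapped by 50% of each. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

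Coordinates are those of build mm10, counted from 1. Genes were assigned from spans of the assembly GRCm38.p6 by the nearest span within 50 kb, among 20373 named genes, since the annotation used here gave no strand and so no transcription start. A region within 1 kb of either end of a span is called a gene end, a region inside a span gene body, and another region within 50 kb intergenic. Of the developmental regions, 16.2% were at gene ends, 45.1% in gene bodies, 25.7% intergenic and 13% without a gene, covering 16826 genes. Of the cultured regions these were 12.4%, 44.9%, 25.8% and 16.9%, covering 17721 genes. Exons, introns and untranslated parts were not told apart.

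Counts were summed per gene over its regions and tested in the same way. The 28 gene lists hold 618 members, of which 617 matched the annotation. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance.

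Named regions were those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a level above the median and no overlap of the libraries of the groups compared. Of these the 10 of smallest p in each direction were taken, or 5 for comparisons among 1w to 8w BM, with 1 region per gene and predicted genes left out. Some results that these rules name are not reported here. At most 4 called members were named per list, and Kit, Ly6a, Ptprc, Alb, Lin28b, Hmga2 and Igf2bp3 always. The summed levels of Firre, Xist, Peg3, Igf2bp1 and Flt3 by stage were chosen after their values were seen. Groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

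Alternatives were DESeq2 1.42.0, its size factors within edgeR, total counts without TMM, cyclic loess offsets (span 0.3, 3 iterations), no filter, a fit of the compared groups alone, the replicate number as a block, thinning to the smallest library, leaving out each library, stricter peaks (−log10 q of at least 5) and other overlaps. For the test over any group, a likelihood ratio test of DESeq2 took the place of its Wald test. Counts without 114 co-varying regions, without the E12.5 PL libraries, and with gene-end regions only, and the count of genes called between the cultured groups, were added after seeing the data. Genes named from the lists were tested under the same alternatives as the regions. Thinning and resampling used the seed 20.

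The test was run on counts simulated at a dispersion of 0.05 with known folds. For E16.5 against E12.5 FL, with 96425 regions in the step, 1 of 67 regions changed by 1.5-fold (1.5%), 9 of 67 by 2-fold (13.4%) and 60 of 66 by 4-fold (90.9%) were recovered, with 1 false call. For co-SHI against SHI, with 143016 regions in the step, these were 1 of 67 (1.5%), 14 of 67 (20.9%) and 63 of 66 (95.5%), with 5 false calls. Depth was 2845113 to 20092146 counts per library, and neither it nor the dispersion was varied.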

Results

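Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in haematopoietic stem and progenitor cells of C57BL/6 mice. The cells carried the LSK phenotype, the lineage-negative, Sca-1-positive, Kit-positive fraction that holds blood stem cells and early progenitors. A developmental series of 26 libraries covered 9 groups: E12.5 PL, E12.5 FL, E16.5 FL, perinatal BM and 1w, 3w, 4w, 6w and 8w BM, with 3 libraries in each group except 3w BM with 2. FL and BM are the usual abbreviations of fetal liver and bone marrow, and PL was not spelled out in the labels. In a separate experiment, per the labels' protocols, E12.5 FL cells were kept for 2 h in basic medium (SHI, 3 libraries) or in medium conditioned by E16.5 hepatocytes (co-SHI, 3 libraries). Total counts over the regions of the developmental table ran from 3681041 to 3968734 in E12.5 FL, 4498323 to 5066732 in E12.5 PL, 3341392 to 3610065 in E16.5 FL and 3388381 to 5471921 in perinatal BM. In marrow after birth the totals ran from 2845113 (1w BM 2) to 10167340 (1w BM 3), the widest spread within a group. The cultured libraries held 7512258 to 11655458 counts in SHI and 14280440 to 20092146 in co-SHI.

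The E12.5 PL cells stood apart from all other cells of the developmental series. PC1 of the 5000 most variable regions held 66.5% of the variance and placed the 3 E12.5 PL libraries at -215.6 to -172.1, while the other 23 libraries lay between -52.4 and 73.5. Across regions, E12.5 FL and E12.5 PL libraries correlated at r = 0.47 to 0.61, against 0.86 to 0.88 among the E12.5 FL libraries. A quasi-likelihood F test in edgeR found that 63716 of 99005 regions (64.4%) differed between any of the 9 groups, and 67229 had an unadjusted p under 0.05. Without the E12.5 PL libraries, the same test called 27584 regions.

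**Figure D1:**
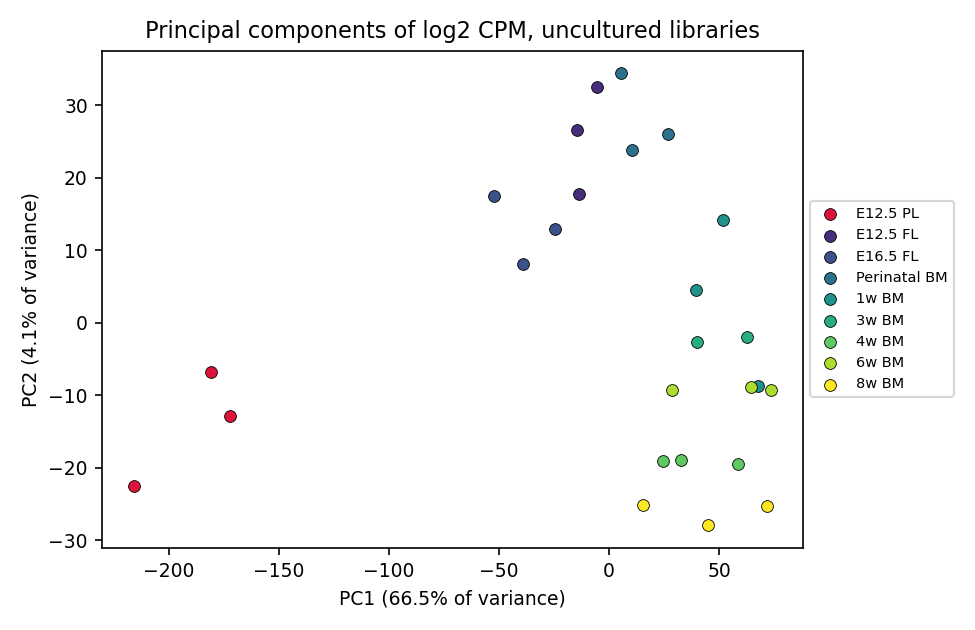
Scores of the 26 libraries of the developmental series on PC1 (x axis, 66.5% of variance) and PC2 (y axis, 4.1%), from log2 CPM of the 5000 most variable regions, with each point a library coloured by group. The 3 E12.5 PL libraries lie at -215.6 to -172.1 on PC1 and all others between -52.4 and 73.5.

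By group mean, E16.5 FL had the shortest deposited peak lists and the cultured groups the longest. Yet co-SHI 2, with 42017 peaks, had fewer than 1w BM 3 (50706) or 8w BM 2 (50806). The mean number of peaks per library was 13846 ± 3989 in E16.5 FL, 21726 ± 2210 in E12.5 FL, 30004 ± 6487 in E12.5 PL and 30535 ± 9017 in perinatal BM (SD, n = 3 each). Later marrow held 36842 ± 10291 (4w BM) to 45644 ± 7089 peaks (3w BM, n = 2), and the cultured libraries held 76210 ± 2590 under the SHI label and 59983 ± 17035 under co-SHI. The ratio of mean peak numbers was 2.21 for perinatal BM over E16.5 FL, 0.64 for E16.5 over E12.5 FL, 0.72 for E12.5 FL over E12.5 PL and 1.87 for 8w BM over E12.5 FL. Each of these gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 libraries against 3 allow, and an adjusted p of 0.25 over 10 comparisons. For 1w BM over perinatal BM the ratio was 1.38 (exact p = 0.2). Between replicates, 70.3% (E12.5 PL) to 84.5% (SHI) of peaks overlapped by at least 1 base.

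**Figure D2:**
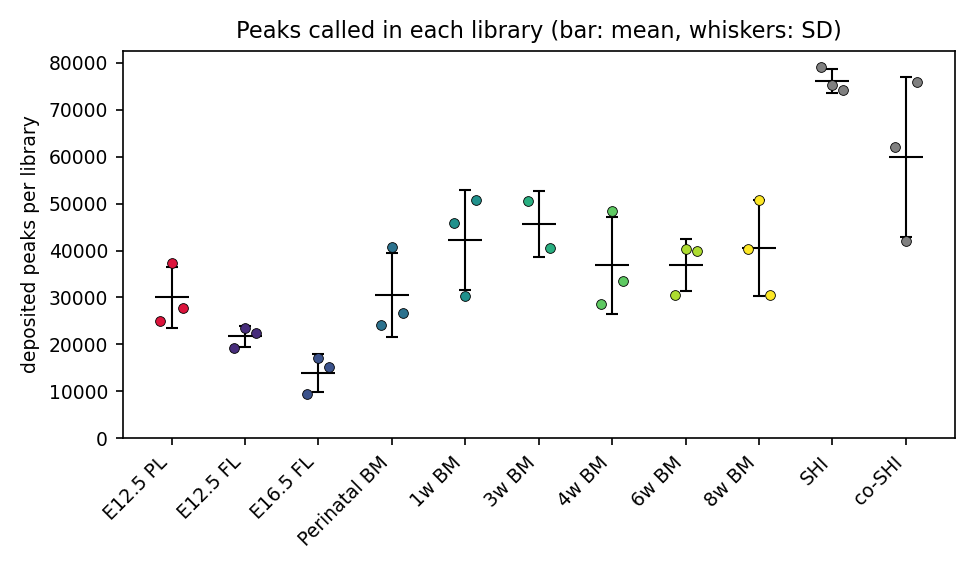
Number of deposited peaks in each library (y axis) by group (x axis), with points for libraries, a bar for the group mean and whiskers for the SD. E16.5 FL libraries hold 9361 to 16999 peaks and the SHI libraries 74151 to 79118.

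E12.5 FL was compared with E12.5 PL, cells of the same embryonic day from the site labelled PL. Most measured genes of the neutrophil (15 of 19), macrophage (14 of 22) and lymphoid lists (17 of 22) were more accessible in E12.5 FL. In E12.5 PL 18 of 26 immediate early genes, 16 of 20 TGF-beta and BMP targets and 15 of 22 endothelial genes were more accessible, lists whose calls were lost with an estimated correlation (adjusted p of 0.11, 0.11 and 0.35). Ptprc, which encodes the pan-leukocyte antigen CD45, stood at 137 ± 16 CPM in E12.5 FL and 43.7 ± 5.3 CPM in E12.5 PL (SD, n = 3 each, log2 fold change 1.64, SE 0.12, adjusted p = 4.5e-14). Flt3, the receptor of early lymphoid and dendritic progenitors, was higher (log2 fold change 1.86, SE 0.12, adjusted p = 1.1e-15). So was Runx1, a transcription factor needed for blood stem cell emergence (1.07). Kit, the stem cell factor receptor, was lower in E12.5 FL, at 96.4 ± 18 against 157 ± 16 CPM (log2 fold change -0.71, adjusted p = 6.2e-06), a direction that turned with regions at gene ends only (0.2, adjusted p = 0.29). Higher too were Hmga2, a chromatin protein of the fetal program (log2 fold change 0.78), and Alb, the hepatocyte albumin gene (0.81, adjusted p = 0.0047). Lin28b (0.3), Igf2bp3 (-0.08) and Ly6a (-1.05, 1 region) had log2 fold changes that did not pass the test, though Ly6a passed with loess offsets (-1.42, adjusted p = 0.025) and without E12.5 FL 1 (-1.67, adjusted p = 0.042).

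Of the neutrophil and myeloid progenitor genes, 15 of 19 were higher in E12.5 FL (15 adjusted over the list alone, camera adjusted p = 1.4e-07), among them Itgam (log2 fold change 1.8), an integrin of myeloid cells, and Ltf (2.22), the granule protein lactoferrin. Of the macrophage and dendritic genes, 14 of 22 were higher (16 adjusted over the list alone, camera adjusted p = 1e-07), including Adgre1 (2.25), which encodes F4/80. Of the lymphoid priming and B cell genes, 17 of 22 were higher (17 adjusted over the list alone, camera adjusted p = 1.5e-08), including Ikzf1 (1.6) and Ighm (2.29). With an estimated correlation these 3 lists kept their calls, with adjusted p of 0.00053, 0.00012 and 0.00012. HSPC identity genes were higher in 14 and lower in 3 of 27 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00095, adjusted p = 0.043 with an estimated correlation), with Lmo2 at 1.16 and the signalling receptor Cd48 at 1.77. Erythroid genes were higher in 11 of 17 (11 adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.082 with an estimated correlation), led by Nfe2 (1.41) and the beta-globin gene Hbb-bt (1.96). Megakaryocyte genes were higher in 10 and lower in 2 of 17 (the same counts adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.057 with an estimated correlation). T and NK cell genes were higher in 12 of 20 (12 adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.11 with an estimated correlation). Mast cell and basophil genes, with 7 higher and 2 lower of 13 (7 and 3 adjusted over the list alone), were not called by camera (adjusted p = 0.63) but were by fry (higher, adjusted p = 0.00057).

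Camera called 5 lists lower in E12.5 FL, and none of these calls held with an estimated correlation. Immediate early genes were lower in E12.5 FL in 18 and higher in 1 of 26 (19 and 1 adjusted over the list alone, camera adjusted p = 6.5e-06, adjusted p = 0.11 with an estimated correlation), with Klf4 at -1.26 and Atf3 at -1.34, while Dusp2 was higher at 1.23. TGF-beta and BMP targets were lower in 16 and higher in 2 of 20 (the same counts adjusted over the list alone, camera adjusted p = 0.00032, adjusted p = 0.11 with an estimated correlation), including the inhibitory Smad6 (-0.74). Cholesterol and fatty acid synthesis genes were lower in 10 of 20 (10 adjusted over the list alone, camera adjusted p = 0.0044, adjusted p = 0.11 with an estimated correlation), led by the desaturase Scd1 (-1.32). Quiescence and cyclin inhibitor genes were lower in 9 and higher in 1 of 17 (the same adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.11 with an estimated correlation), including Cdkn1a (-0.96), which encodes p21. Endothelial genes were lower in 15 and higher in 1 of 22 (the same adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.35 with an estimated correlation), including the receptors Tek (-1.52) and Kdr (-1.09). With regions at gene ends only, the endothelial and quiescence calls ended, at adjusted p of 0.84 and 0.09, as did the gene calls of Smad6 (-0.25), Tek (-0.58), Kdr (-0.22) and the keratin Krt18 (-0.47) and that of Cdkn1a, which turned to 0.26. Trophoblast keratins Krt8 (-1.01), Krt18 (-1.09) and Krt19 (-2.21) were lower in E12.5 FL, though camera did not call that list (6 lower and 1 higher of 18, the same adjusted over the list alone, adjusted p = 0.15), which fry called lower (adjusted p = 0.0053). Stromal and mesenchymal genes went both ways, with 6 higher and 5 lower of 20, also adjusted over the list alone. Their median log2 fold change was -0.16, with a mean of 0.03 and a camera direction of lower (adjusted p = 0.79).

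Camera did not call the other fixed lists for E12.5 FL against E12.5 PL, and of all 16825 genes 4499 were higher and 3804 lower. By fry 20 of 28 lists were called, among them, of these others, homing and NF-kB genes (higher, adjusted p of 0.0025 and 0.024), interferon genes (higher, 0.026), and glycolysis (lower, 2.6e-06), chromatin regulators (lower, 0.0025) and JAK-STAT targets (lower, 0.034). Higher and lower counts were 4 and 6 of 19 for the fetal-type program (camera adjusted p = 0.68), 9 and 8 of 25 for the adult-type program (0.69), 6 and 3 of 17 for hepatocyte genes (0.79) and 9 and 8 of 22 for homing and adhesion genes (0.59), where the median was -0.02, the mean 0.09 and the camera direction higher. They were 2 and 8 of 24 for chromatin regulators (0.052), 1 and 7 of 20 for glycolysis (0.1), 4 and 7 of 21 for JAK-STAT target genes (0.16) and 6 and 2 of 18 for interferon response genes (0.69). They were 8 and 2 of 22 for NF-kB and inflammatory genes (0.55), where the median was -0.03, the mean 0.25 and the camera direction higher, and 3 and 3 of 23 for oxidative phosphorylation (0.55). They were 4 and 2 of 24 for cell cycle and replication (0.68), 1 and 1 of 12 for Hox genes (0.84), with a mean of 0.04 and a camera direction of lower, and 2 and 3 of 21 for inert reference genes (0.7). The inert genes had a median of -0.06, a mean of 0.05 and a camera direction of lower. Adjusted over the list alone, the counts were 5 and 6 for the fetal-type program, 10 and 8 for the adult-type program, 2 and 3 for oxidative phosphorylation, 3 and 2 for cell cycle and replication and 1 and 1 for the inert genes. For the other 8 of these lists they did not differ from those over all genes.

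Region by region, E12.5 FL and E12.5 PL differed at 48927 of 99005 regions by edgeR, with 22827 more accessible in E12.5 FL and 26100 less. Gene ends made up 6.7% of the regions higher in E12.5 FL and 28.4% of those lower, against 16.2% of the regions tested, and 44.2% ± 1.7 of E12.5 PL counts lay near gene ends against 37% ± 1.2 in E12.5 FL (SD, n = 3 each). An intergenic region 9692 bp from Notch1, a receptor that directs T cell fate, held 36 ± 4.2 CPM in E12.5 FL and 5.03 ± 1.7 CPM in E12.5 PL (chr2:26513221-26513807, log2 fold change 2.83, SE 0.24, adjusted p = 6.6e-14). A region in the body of Adgrg1, which encodes the adhesion receptor GPR56, was higher by 2.61 on the log2 scale (chr8:94984911-94985666, SE 0.22). Regions in Bcr (2.86), Sh2d5 (2.95), Fancc (2.89) and Ptpre (2.56), and intergenic regions nearest to Utp18 (2.66), Spata48 (2.64), Pex5 (2.39) and Pebp4 (2.37), were the other named regions that were higher. An intergenic region 5695 bp from Klf9, a Krüppel-like transcription factor, held 18 ± 1.9 CPM against 104 ± 4.9 CPM (chr19:23134729-23136332, log2 fold change -2.52, SE 0.17, adjusted p = 2.4e-16). A region at the end of Atf3, a stress-induced transcription factor, had a log2 fold change of -2.71 (chr1:191182256-191183841), and a region in Sptbn1, a beta-spectrin gene, of -4.84 (chr11:30160993-30161493). Regions of Rcan1 (-2.96), Ptms (-3.56), Tspan9 (-4.12), Lekr1 (-2.23), Tsc22d2 (-3.66), Pakap (-3.59) and Rbfox2 (-2.38) were lower too. The share of calls that were higher was 46.7% with TMM, 35.4% with DESeq2 size factors, 34.8% in DESeq2 and 63.2% with total counts. The median log2 fold change of all regions moved from 0.089 to -0.122 with size factors, 0.377 with total counts and -0.022 with loess offsets. Loess offsets lowered the number of calls to 31970.

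E16.5 FL was compared with E12.5 FL to follow the cells within the fetal liver, where few differences passed the test. The region that did lies in the body of Slc8a1, which encodes a sodium-calcium exchanger, at 6.5 ± 2.7 CPM in E16.5 FL and 0.768 ± 0.67 CPM in E12.5 FL (chr17:81480276-81480833, n = 3 each, log2 fold change 3.01, SE 0.5, adjusted p = 0.012). Kit (log2 fold change 0.21, SE 0.12), Ptprc (-0.12, SE 0.11), Lin28b (-0.36, SE 0.17), Igf2bp3 (-0.06, SE 0.14), Hmga2 (-0.01, SE 0.09), Alb (-0.05, SE 0.23) and Ly6a (0.71, SE 0.59) did not pass, with adjusted p of 0.63 or more. The edgeR test called 1 region higher and 0 lower of 99005, with 7190 at unadjusted p under 0.05, and DESeq2 called 33 regions. Camera called 0 of 28 lists, with 5 at unadjusted p under 0.05, and fry called 0. The Slc8a1 call ended without E16.5 FL 2 or 3 or without E12.5 FL 2 or 3. The number of calls was 22 without E16.5 FL 1, 3 without E12.5 FL 1 and 0 without any other of the 6 libraries, and 2 when the groups were fitted alone. Camera called 5 lists without E12.5 FL 3 and 2 without E16.5 FL 1.

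Perinatal BM was compared with E16.5 FL, the step from fetal liver to marrow. Of the fixed lists camera called 7, each with a minority of members past the threshold, and none held with an estimated correlation. Among all 16825 genes 1552 were higher and 1148 lower in perinatal BM. Ski and Skil, which encode repressors of SMAD signalling, rose by 0.93 (SE 0.12) and 0.9 (SE 0.11) on the log2 scale (edgeR adjusted p = 6.9e-06 each), and the inhibitory Smad7 by 0.7. Of the TGF-beta and BMP targets, 9 of 20 rose (9 adjusted over the list alone, camera adjusted p = 6.4e-05, adjusted p = 0.21 with an estimated correlation). Of the immediate early genes 7 of 26 rose (11 adjusted over the list alone, camera adjusted p = 0.00028, adjusted p = 0.41 with an estimated correlation), among them the nuclear receptor gene Nr4a1 (0.67) and Egr2 (0.43). Cholesterol and fatty acid synthesis genes rose in 6 of 20 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0071, adjusted p = 0.36 with an estimated correlation), led by Hmgcs1 (0.78), which acts at the start of sterol synthesis. JAK-STAT target genes rose in 5 of 21 (5 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.41 with an estimated correlation), with Bcl3 at 0.73. Glycolysis genes rose in 5 of 20 (5 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.21 with an estimated correlation), with Bnip3 at 0.46. Hox genes fell in 3 of 12 (4 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.46 with an estimated correlation), with Hoxb9 at -1.11 and Hoxa5 at -1.29. Trophoblast genes fell in 2 of 18 (0 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.36 with an estimated correlation), the members being Cdx2 (-0.39) and Ascl2 (-0.55). Igf2bp1, an RNA-binding protein gene of the fetal program, fell by 1.29 (52 ± 14 to 21.3 ± 5.2 CPM), and Ptprc (0.35), Flt3 (0.49) and the progenitor antigen Cd34 (0.45) rose. Kit (-0.26), Ly6a (-0.04), Alb (-0.18), Lin28b (0.07), Hmga2 (-0.2) and Igf2bp3 (-0.19) did not pass, though Kit (-0.38) and Hmga2 (-0.37) passed with loess offsets. Of the 74 genes called under the rule for named genes, 38 lost the call with loess offsets, 47 without E16.5 FL 1 and 45 without perinatal BM 2. Those given here were Ptprc, Cd34, Egr2, Bnip3, Hoxa5 and Ascl2 with loess offsets, Ptprc, Cd34, Bnip3, Cdx2 and Ascl2 without E16.5 FL 1, and Ptprc, Hoxa5 and Cdx2 without perinatal BM 2. With gene ends only Ptprc turned to -0.01 and the calls of Cd34, Cdx2 and Ascl2 ended. Ptprc was also lost with total counts and without E16.5 FL 3, and Cdx2 and Ascl2 with DESeq2 size factors, in a fit of these groups alone, without E16.5 FL 2 and without perinatal BM 1. Cdx2 was lost too at thinned depth and without E16.5 FL 3, and Ascl2 without perinatal BM 3. By fry 10 lists were called, not the Hox list (adjusted p = 0.067) but also the megakaryocyte and homing lists (higher, 0.03 each) and the fetal-type and stromal lists (lower, 0.018 and 0.011). With loess offsets none of the 7 camera calls passed, at adjusted p of 0.061 for TGF-beta targets, 0.25 for immediate early genes, 0.21 for cholesterol genes, 0.73 for JAK-STAT targets, 0.72 for glycolysis, 0.21 for Hox genes and 0.15 for trophoblast genes. With regions at gene ends only, glycolysis (0.56), cholesterol (0.053), immediate early (0.088) and trophoblast genes (0.053) did not pass. Calls also ended without perinatal BM 3 for glycolysis (0.081) and JAK-STAT targets (0.11), without perinatal BM 2 for Hox genes (0.11) and without E16.5 FL 1 for trophoblast genes (0.13).

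Across the genome 7948 regions differed between perinatal BM and E16.5 FL, 6598 higher and 1350 lower, and gene ends made up 38.2% of the higher and 10.7% of the lower. A region in Arid3a, a DNA-binding protein gene, stood at 34.1 ± 22 CPM in perinatal BM and 6.08 ± 2.3 CPM in E16.5 FL (chr10:79936801-79937594, n = 3 each, log2 fold change 2.51, SE 0.31, adjusted p = 9.1e-07). A region in Eef2k, the kinase of elongation factor 2, had a log2 fold change of 1.58 (chr7:120851381-120852151), and a region in Ski of 1.54 (chr4:155200710-155201332). Regions of Nid1 (2.21), Wfs1 (1.35), Pkd1l2 (2.43), Irf2bpl (1.74), Dab2ip (1.39), Asprv1 (1.7) and Mrpl14 (1.95) were also higher. A region 1801 bp from the histone gene H3f3b fell from 70.9 ± 12 to 14.6 ± 6.5 CPM (chr11:116019274-116021045, log2 fold change -2.29, SE 0.29, adjusted p = 1.2e-06), and a region at the end of the noncoding RNA gene Malat1 had -2.24 (chr19:5794638-5795531). Regions of Crlf2 (-1.38), Cdk8 (-1.1), Filip1l (-1.14), Il1rapl1 (-1.5), Camk1d (-1.13), Sfi1 (-1.02), Apbb1ip (-1.15) and Atp6v1h (-1.71) fell too. No screen for artefact signal was made, and the Cdk8, Filip1l and Sfi1 regions held 226 to 492 CPM in E16.5 FL. The share of calls that were higher was 83% with TMM, 59.2% with total counts, 62.1% with these groups fitted alone and 50.5% with loess offsets. The last 3 settings called 4773, 5067 and 1778 regions. The median log2 fold change moved from -0.041 to -0.229 with total counts, and 3017 regions were called without perinatal BM 2 and 2791 without E16.5 FL 1.

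1w BM was compared with perinatal BM, the step into the week after birth. Few genes of the fixed lists passed, and none of the 6 list calls held with an estimated correlation. Nr4a1, an immediate early nuclear receptor gene, rose by 0.53 on the log2 scale (SE 0.11, edgeR adjusted p = 0.019), and Peg3, a zinc finger gene expressed from the paternal allele, fell by 0.83 (126 ± 29 to 71 ± 4.8 CPM, SD, n = 3 each, adjusted p = 0.0019). With gene ends only both gene calls ended, at adjusted p of 0.073 for Nr4a1 and 0.58 for Peg3. Both ended without perinatal BM 1 (0.32 and 0.1). That of Nr4a1 also ended without 1w BM 1 (0.24). Nr4a1 was the member called in the immediate early list (1 of 26, 4 adjusted over the list alone, camera adjusted p = 3.4e-07, adjusted p = 0.2 with an estimated correlation) and in the adult-type program (1 of 25, 4 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.2 with an estimated correlation). Peg3 was the member called in the fetal-type program (1 lower of 19, 2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0083, adjusted p = 0.2 with an estimated correlation). No single member passed over all genes in 3 further lists. They were the JAK-STAT list (higher, 0 members adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.43 with an estimated correlation) and the NF-kB list (higher, 0 members adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.26 with an estimated correlation). The trophoblast list was lower (2 members lower adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.2 with an estimated correlation). By camera 10 lists had an unadjusted p under 0.05, and fry called 0 of 28 lists. Kit (-0.02), Ptprc (-0.07), Lin28b (-0.15), Igf2bp3 (-0.14), Hmga2 (0.06), Alb (-0.02) and Ly6a (-0.67) did not pass. Of 179 regions called, 32 were higher, among them a region at the end of Nr4a1 (chr15:101275117-101276185, log2 fold change 1.33, SE 0.23, adjusted p = 0.0014), which was lost without 1w BM 1, and a region in Mgat4b (chr11:50232833-50233426, 1.52). Further higher regions lay at Rhbg (2.49), Spag9 (2.59), Bahcc1 (1.13), Phlpp1 (1.85), Dap (1.36), Neat1 (1.64), Rgs1 (1.41) and Dpysl3 (1.2). Without 1w BM 1 the calls at Bahcc1, Phlpp1, Dap, Neat1, Rgs1 and Dpysl3 ended, and without perinatal BM 1 these and that at Spag9. Spag9 was also lost without 1w BM 2, Bahcc1, Phlpp1, Neat1 and Dpysl3 without perinatal BM 3, and Dap and Rgs1 without perinatal BM 2. Thinning ended the calls at Rhbg and Rgs1, DESeq2 and loess offsets that at Neat1, and a fit of these groups alone those at Rgs1 and Dpysl3. The lower regions at Btd (-2.2), Nkain2 (-3.22), Clstn2 (-3.18), Tbk1 (-2.55), Slc39a11 (-1.4), Sulf1 (-2.6), Sema4b (-2.47), Fras1 (-2.66) and Itprip (-2.39) are among 114 co-varying regions, whose levels correlated across libraries at r above 0.85 with the mean of a set of 65 regions. Without the 114 regions 97 calls were left. Sulf1, Sema4b and Itprip lost their calls without 1w BM 1. DESeq2 called 90 regions, 31.1% of them higher against 17.9% in edgeR, and did not call Tbk1, Sema4b, Fras1 and Itprip. The count was 18 without 1w BM 1, 8 higher and 10 lower, and 44 without perinatal BM 1. List calls ended without 1w BM 1 (adult-type, fetal-type, trophoblast), perinatal BM 1 (JAK-STAT, NF-kB, trophoblast), perinatal BM 3 (fetal-type, trophoblast) and 1w BM 3 (JAK-STAT, NF-kB). The adjusted p went up to 0.051, 0.063, 0.15, 0.54 and 0.24 for the adult-type, fetal-type, trophoblast, JAK-STAT and NF-kB lists, and 3 lists were called without 1w BM 1 and 3 without perinatal BM 1. With gene ends only, the fetal-type (0.11), JAK-STAT (0.15), NF-kB (0.066) and trophoblast (0.15) calls ended, and with loess offsets the JAK-STAT call (0.072).

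3w BM was compared with 1w BM, where Peg3 fell again. The Peg3 locus dropped from 71 ± 4.8 CPM (n = 3) to 29.1 ± 4 CPM (n = 2), a log2 fold change of -1.3 (SE 0.17, edgeR adjusted p = 3.5e-05), and its strongest region, in the gene body, from 40.8 ± 3.7 to 8.73 ± 1.2 CPM (chr7:6727243-6728975, log2 fold change -2.25, SE 0.23, adjusted p = 8.9e-09). Igf2bp3 (-0.66, adjusted p = 0.097) and Lin28b (-0.63, adjusted p = 0.29), RNA-binding protein genes of the fetal program, did not pass on their own. Peg3 was the member called among 19 fetal-type genes (3 lower adjusted over the list alone, camera adjusted p = 0.00023, adjusted p = 0.091 with an estimated correlation). The cytokine gene Il1b rose by 1 on the log2 scale (SE 0.2, adjusted p = 0.023). The Peg3 gene call ended with gene ends only (-0.43, adjusted p = 0.73) and without 3w BM 1 (adjusted p = 0.069). That of Il1b ended without any of the 5 libraries except 1w BM 2 (up to 0.55), at thinned depth (0.15) and in a fit of these groups alone (0.071). Igf2bp3 passed in DESeq2 (0.038) and in that fit (0.029). The immediate early (lower, camera adjusted p = 0.01, adjusted p = 0.77 with an estimated correlation) and HSPC identity lists (lower, camera adjusted p = 0.044, adjusted p = 0.37 with an estimated correlation) had no member past the threshold, and 1 and 2 lower adjusted over the list alone. Neither passed with gene ends only (0.32 and 0.71), and fry called 0 lists. Hmga2 (-0.13), Kit (0.01), Ptprc (0), Alb (-0.79) and Ly6a (-0.11) did not pass. The test called 88 regions, 57 higher and 31 lower. A region in Adgrg1 rose from 27.4 ± 4 to 92.9 ± 20 CPM (chr8:95012360-95013113, log2 fold change 1.74, SE 0.23, adjusted p = 1.6e-05), and regions of Apool (1.22), Ang6 (2.12), Ssr3 (1.87) and Itpr1 (2.61) rose. Regions of Fmn1 (-2.29), D7Ertd443e (-2.37), Dusp22 (-1.53) and Aopep (-3.35) fell. These 4 calls ended without 3w BM 1 and without 3w BM 2, and that of Ang6 without 3w BM 2. Dusp22 was also lost without 1w BM 2, and Aopep without 1w BM 3, at thinned depth and in a fit of these groups alone. DESeq2 called 185 regions, 45.4% of them higher against 64.8% in edgeR, and 16 were called without 3w BM 1 (81.2% higher), 13 without 3w BM 2 (84.6% higher), 55 without 1w BM 1 and 41 without 1w BM 2. With a 3w BM library left out, 1 library stood for that group and was assumed to vary like the other groups. The immediate early call ended without 1w BM 1 or 3 or 3w BM 1, with adjusted p up to 0.35, and the HSPC identity call without every library but 1w BM 1, up to 0.14. The lists called numbered 1 without 1w BM 3 and 1 without 3w BM 1.

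4w BM differed from 3w BM at 8 regions. An intergenic region 20428 bp from Insig1, which encodes a brake on sterol synthesis, rose from 6.55 ± 1.8 (n = 2) to 25 ± 8.3 CPM (n = 3, chr5:28098352-28099828, log2 fold change 1.9, SE 0.36, adjusted p = 0.021). The 5 named regions that fell, at Fstl1 (-3.69), Lmo3 (-3.57), Zfp791 (-3.54), Kat6b (-3.07) and Itprip (-3.07), are all among the 114 co-varying regions, and 1 call lay outside these. Igf2bp3 (-0.31), Lin28b (-0.24), Hmga2 (-0.08), Kit (-0.12), Ptprc (-0.23), Alb (-0.16) and Ly6a (-0.28) did not pass. Camera called 0 of 28 lists, with 4 at unadjusted p under 0.05, and fry called 0, while 3 were called without 3w BM 2, 1 without 4w BM 1 and 2 without 4w BM 3. Of 99005 regions edgeR called 8, with 4102 at unadjusted p under 0.05, while DESeq2 called 0 and a fit of these groups alone 101. The count was 4 without 4w BM 1 and 0 without any other of the 5 libraries, where a lone 3w BM library was assumed to vary like the other groups, and DESeq2 or leaving out 4w BM 2 or 3 or either 3w BM library ended each named call, as did leaving out 4w BM 1 for Fstl1, Zfp791 and Kat6b.

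6w BM was compared with 4w BM, where 8 of 26 immediate early genes rose, in a list whose call was lost with an estimated correlation (adjusted p = 0.21). Jun rose 3.38-fold (log2 fold change 1.76, SE 0.29), Fosb 1.93-fold (0.95, SE 0.16) and Fos 1.91-fold (0.93, SE 0.16), with edgeR adjusted p of 0.001, 0.001 and 0.0024, and Zfp36, whose product destabilises inflammatory mRNAs, rose 1.86-fold (0.9). Without 6w BM 3 each of the 7 genes called under the rule for named genes lost the call, with adjusted p of 0.07 for Jun, 0.082 for Fosb, 0.18 for Fos and 0.082 for Zfp36. That of Fos also ended without 6w BM 1 (0.05). Adjusted over the list alone 10 immediate early genes rose (camera adjusted p = 3.3e-11). Adult-type genes rose in 6 of 25 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.48 with an estimated correlation), and Jun, Zfp36, Fos and Nr4a1 (0.56) of these are immediate early genes as well. The Nr4a1 call ended without any of the 6 libraries except 6w BM 2 (up to 0.35). The fetal-type program (lower, 1 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.36 with an estimated correlation) and chromatin regulators (lower, 2 lower adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.48 with an estimated correlation) had no member past the threshold over all genes, and fry called 0 lists. Igf2bp3 (-0.66, adjusted p = 0.071), Hmga2 (-0.26), Lin28b (-0.04), Kit (-0.01), Ptprc (-0.04), Alb (0.09) and Ly6a (-0.15) did not pass, though Igf2bp3 passed with gene ends only (-1.57, adjusted p = 0.0019), without 6w BM 1 (0.0091), in DESeq2 (0.028) and in a fit of these groups alone (0.016). The adult-type call ended with loess offsets (0.1) and without 4w BM 2, 6w BM 1 or 6w BM 3 (up to 0.28), the fetal-type call without 4w BM 1 or 6w BM 3 (up to 0.075), and the chromatin call with gene ends only (0.27). Without 6w BM 3, 2 lists were called.

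6w and 4w BM differed at 174 regions, 137 higher and 37 lower. The named lower regions of smallest p were X-linked. A region in Firre, a noncoding RNA gene, fell from 15 ± 0.77 to 0.319 ± 0.28 CPM (chrX:50599681-50600723, n = 3 each, log2 fold change -5.42, SE 0.58, adjusted p = 1.8e-08). A region 40983 bp from Pls3 had -5.72 (chrX:75744407-75744933) and a region in Xist, whose RNA silences an X chromosome, -4.68 (chrX:103481466-103482015). Summed over the gene, Firre stood at 53.2 ± 2.6 CPM in 6w BM and 46.9 ± 4.7 in 8w BM, and between 132 ± 25 and 192 ± 7.8 CPM in the other groups. Xist stood at 13.1 ± 2.4 CPM in 6w BM, 14 ± 0.49 in 8w BM and between 21 ± 3.1 and 36.4 ± 5.6 CPM in the others. Single earlier libraries were low too, with Xist at 15.2 and Firre at 84.7 CPM in 1w BM 3, and 19.6 and 95.2 CPM in perinatal BM 3. Animal sex was not tested, so these levels cannot be ascribed to age. A region at the end of Igf2bp3 (chr6:49215210-49215776, -2.03) and an intergenic region near Crhbp (-2.27, lost without 6w BM 1, 6w BM 2 or 4w BM 2) were lower. Regions of Fosb (chr7:19301004-19302533, 2.24) and the noncoding RNA gene Neat1 (chr19:5839658-5840170, 2.33) were higher, as were those at Kat6b (4.07), Fstl1 (4.35) and Itprip (3.68), which are among the 114 co-varying regions. Outside these 102 regions were called, 65 higher and 37 lower. A fit of these groups alone called 434, and the count was 91 without 6w BM 3, 108 without 4w BM 2 and 109 without 4w BM 3.

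8w BM was compared with 6w BM, where 2 of 26 immediate early genes fell with TMM scaling and none of them with loess offsets. Fosb fell by 0.8 (SE 0.16) and Klf2, a transcription factor of quiescence and cell trafficking, by 0.74 (SE 0.14) on the log2 scale (edgeR adjusted p = 0.044 each). Both calls ended with loess offsets (0.069 each), where edgeR called 0 genes and 588 had an unadjusted p under 0.05. Both also ended with total counts (0.065 each) and without any of the 6 libraries except 6w BM 2 (up to 1 for Fosb and 0.72 for Klf2). That of Fosb ended in DESeq2 (0.16). In the immediate early list 10 were lower adjusted over the list alone (camera adjusted p = 7.9e-18, adjusted p = 0.036 with an estimated correlation). The adult-type program had 0 members called over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.38 with an estimated correlation), with a median of 0.02, a mean of -0.14 and a camera direction of lower, and its call ended without 6w BM 1 or 3 (up to 0.13). Without 6w BM 3, 1 list was called. By fry, 0 of 28 lists passed. Lin28b (-0.24), Igf2bp3 (0.07), Hmga2 (0.08), Kit (0.09), Ptprc (0.17), Alb (0.09) and Ly6a (0.35) did not pass. Of 96 regions called, 91 were lower, and the 5 named, at Kat6b (chr14:21613305-21613917, -4.67, SE 0.55), Fstl1 (-5.29), Itprip (-4), Mapk4 (-4.03) and Elmod3 (-3.64), are among the 114 co-varying regions. Outside these 19 regions were called, 5 higher and 14 lower, among them Smim14 (1.66) and Crhbp (2.13), neither of which passed with loess offsets or at thinned depth. Smim14 was lost without each of the 6 libraries in turn, and Crhbp in DESeq2 and without any of them except 8w BM 3. DESeq2 called 44 regions, and the count was 54 without 8w BM 1, 34 without 8w BM 2 and 63 without 6w BM 3.

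**Figure D3:**
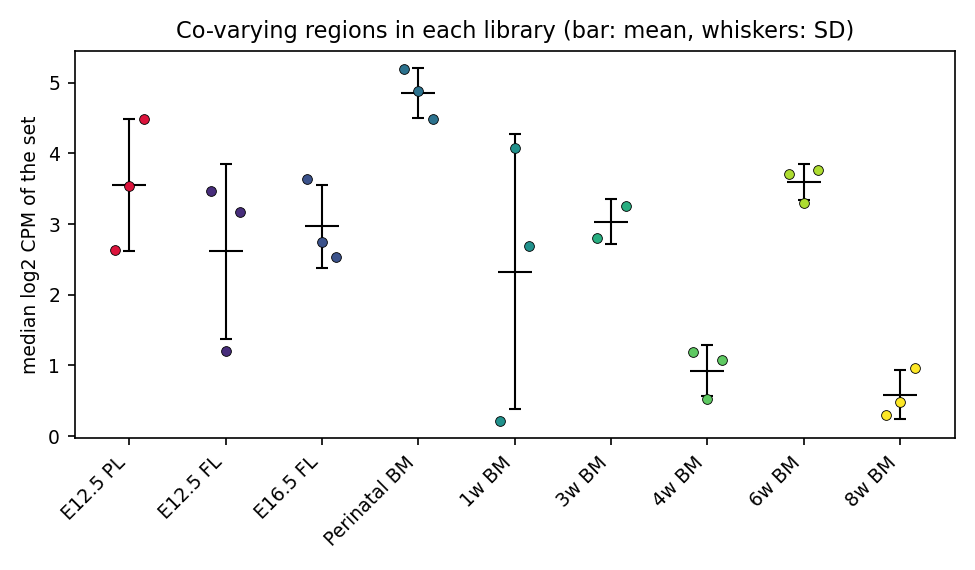
Median log2 CPM over the 65 co-varying regions (y axis) in each library of the developmental series by group (x axis), with a bar for the group mean and whiskers for the SD. The 3 perinatal BM libraries lie at 4.49 to 5.19, those of 8w BM at 0.3 to 0.97, and those of 1w BM from 0.22 to 4.07.

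8w BM, the last stage, was compared with E12.5 FL. Xist (28.5 to 14 CPM) and Firre (132 to 46.9) fell, so untested sex may play a part. Of 19 genes of the fetal-type program 14 fell, a call that held with an estimated correlation (adjusted p = 0.00061). Peg3 fell from 182 ± 41 to 25.1 ± 1.6 CPM (SD, n = 3 each, log2 fold change -2.86, SE 0.16, adjusted p = 3.7e-17) and Igf2bp3 from 190 ± 29 to 48.8 ± 6.7 CPM (-1.96, SE 0.15, adjusted p = 2e-12). Igf2bp1, at 61 ± 10 CPM in E12.5 FL, fell by 2.31 on the log2 scale (SE 0.25). Lin28b, which keeps fetal blood stem cells in their fetal state, fell from 65.3 ± 4.2 to 21.9 ± 2.4 CPM (-1.58, SE 0.18). Hmga2 fell by 0.55 (213 ± 21 to 145 ± 5.6 CPM, adjusted p = 3.2e-05) and Alb by 1.02 (25.5 ± 4.4 to 12.4 ± 1.9 CPM, adjusted p = 0.0014), while Kit (-0.1), Ptprc (0.06) and Ly6a (-0.19) did not pass. In this list 1 gene rose (the same counts adjusted over the list alone, camera adjusted p = 2.5e-12).

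**Figure D4:**
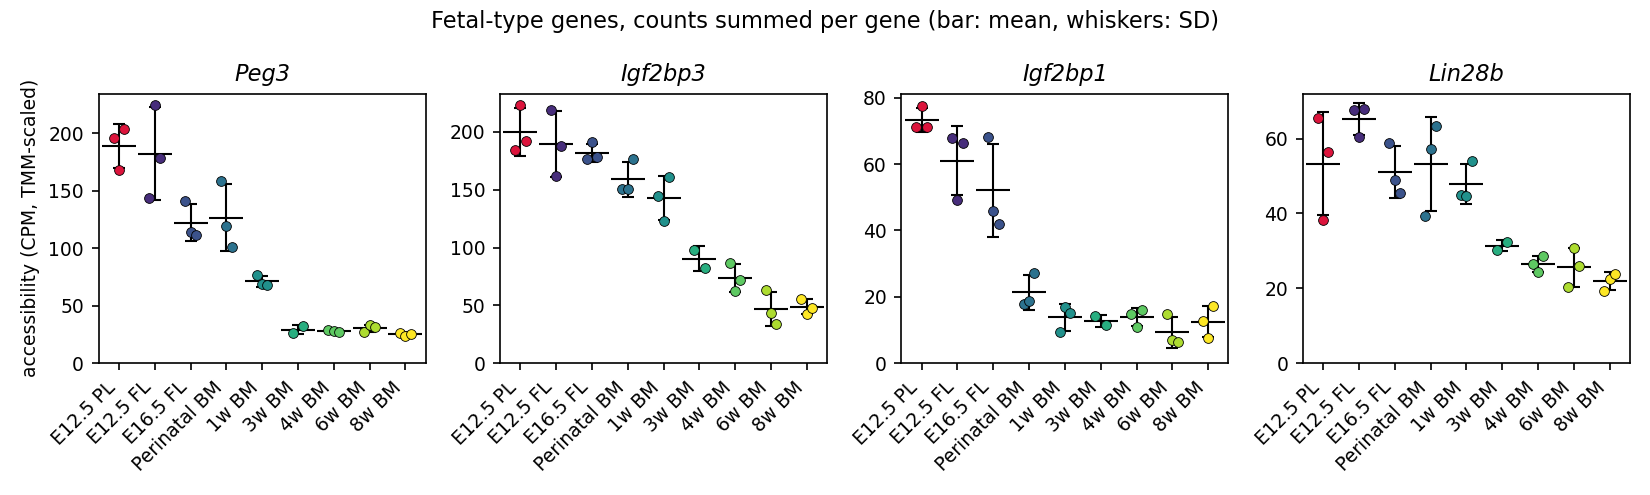
Accessibility of Peg3, Igf2bp3, Igf2bp1 and Lin28b (y axis, TMM-scaled CPM summed over the regions of each gene) in each library of the developmental series by group (x axis), with a bar for the group mean and whiskers for the SD. Peg3 lies at 182 ± 41 CPM in E12.5 FL, 71 ± 4.8 in 1w BM and 29.1 ± 4 in 3w BM.

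Between E12.5 FL and 8w BM camera called 9 lists higher, none of which held with an estimated correlation. Immediate early genes rose in 17 of 26 (19 adjusted over the list alone, camera adjusted p = 7.7e-11, adjusted p = 0.075 with an estimated correlation), with Nr4a1 at 1.01 and Egr1 at 0.99. NF-kB and inflammatory genes rose in 12 of 22 (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.07 with an estimated correlation), with the cytokine genes Il1b at 1.91 and Il6 at 1.6. TGF-beta and BMP targets rose in 10 and fell in 3 of 20 (the same adjusted over the list alone, camera adjusted p = 4.8e-05, adjusted p = 0.11 with an estimated correlation), with Ski at 1.6 and Skil at 1.2. JAK-STAT targets rose in 11 of 21 (11 adjusted over the list alone, camera adjusted p = 0.00021, adjusted p = 0.15 with an estimated correlation), with the cytokine gene Osm at 1.03. Adult-type genes rose in 8 and fell in 1 of 25 (the same adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.15 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 6 of 20 (6 adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.15 with an estimated correlation), with Insig1 at 0.71. Quiescence genes rose in 6 and fell in 3 of 17 (7 and 4 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.15 with an estimated correlation), with Cdkn1a at 0.92 and the imprinted gene Ndn at -1.47. Glycolysis genes rose in 7 and fell in 1 of 20 (the same adjusted over the list alone, camera adjusted p = 0.032, adjusted p = 0.11 with an estimated correlation). Interferon response genes rose in 4 of 18 (4 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.15 with an estimated correlation), with Irf1 at 0.6. Inert reference genes, such as Actb, were not called by camera (adjusted p = 0.091), with 3 higher and 1 lower of 21 (the same adjusted over the list alone), a median of 0.16 and a mean of 0.14, but fry called them higher (adjusted p = 0.026).

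Besides the fetal-type program camera called 4 lists lower, none of which held with an estimated correlation, and did not call the hepatocyte list (3 higher and 2 lower of 17, also adjusted over the list alone, adjusted p = 0.6). Fry called 17 lists, these 14, the inert genes, lymphoid genes (lower, adjusted p = 0.0046) and megakaryocyte genes (higher, 0.031). Hox genes fell in 4 of 12 (5 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.45 with an estimated correlation), with Hoxa5 at -1.92. Trophoblast genes fell in 7 and rose in 1 of 18 (the same adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.15 with an estimated correlation). Endothelial genes fell in 6 of 22 (6 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.49 with an estimated correlation), with Tek at -1.12. Stromal genes fell in 8 and rose in 2 of 20 (9 and 3 adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.11 with an estimated correlation). Of the 14 list calls of 8w BM against E12.5 FL, 8 ended with loess offsets, namely the adult-type (0.069), quiescence (0.39), glycolysis (0.46), cholesterol (0.17), JAK-STAT (0.085), trophoblast (0.069), stromal (0.21) and Hox lists (0.15). With gene ends only the quiescence (0.064), glycolysis (0.15), trophoblast (0.39) and stromal (0.074) calls ended. Calls ended without E12.5 FL 2 for cholesterol (0.074), glycolysis (0.077) and quiescence genes (0.12), without E12.5 FL 3 for Hox genes (0.067), without E12.5 FL 1, E12.5 FL 3 or 8w BM 2 for interferon genes (up to 0.1), and without E12.5 FL 2, E12.5 FL 3, 8w BM 2 or 8w BM 3 for stromal genes (up to 0.082).

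In all, 16244 regions differed between 8w BM and E12.5 FL, 10602 higher and 5642 lower, and gene ends made up 29.5% of the higher and 15.4% of the lower. The region in the body of Adgrg1 that rose between 1w and 3w BM stood at 115 ± 17 CPM in 8w BM and 10.1 ± 4.4 CPM in E12.5 FL (chr8:95012360-95013113, log2 fold change 3.49, SE 0.24, adjusted p = 2.1e-16). The Klf9 region rose to 92.3 ± 15 CPM from 18 ± 1.9 (log2 fold change 2.36). The Arid3a (4.02), Nr4a1 (3.2), Ski (2.49) and Mrpl14 (3.22) regions of the earlier steps rose too. Regions in Ctif (3.98), Ccdc88c (3.58) and Rftn1 (2.7) and at the end of Rgs1 (chr1:144243262-144244691, 3.05), a regulator of chemokine receptor signalling, rose. The Peg3 region fell from 110 ± 25 to 7.51 ± 1.3 CPM (chr7:6727243-6728975, log2 fold change -3.87, SE 0.21, adjusted p = 1.4e-21), and a region at the end of the neighbouring imprinted gene Zim1 had a log2 fold change of -3.32 (chr7:6696277-6696831). A region 2545 bp from Igf2bp3 had -2.43 (chr6:49217671-49218357), and regions at Dsg2 (-3.95), Acss3 (-3.43), Trappc6b (-1.96), Lrrc7 (-2.17), Cecr2 (-1.76), Itgbl1 (-3.46) and Synpr (-3.85) fell. The share of calls that were higher was 65.3% with TMM, 55.7% with DESeq2 size factors, 55.2% in DESeq2, 43% with total counts and 50.3% with loess offsets. Total counts moved the median log2 fold change from -0.052 to -0.248. Without 8w BM 2, 9605 regions were called.

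The cultured cells were compared for effects of 2 h in hepatocyte-conditioned medium. Each of the 6 cultured peak lists correlated best with a count column of the other group (r = 0.26 to 0.41), while all 26 lists of the developmental series correlated best with the column of their own name. The groups are given as labelled in the count table. By the labels of the peak lists every direction is the opposite. Of 19 interferon response genes 9 were lower in the libraries labelled co-SHI, in a list whose call was lost with an estimated correlation (adjusted p = 0.62). Lower too was Ly6a, which encodes the stem cell antigen Sca-1 and is itself interferon-inducible (log2 fold change -0.94, SE 0.16, edgeR adjusted p = 0.0064). Oasl2 (-0.67), the transcription factor genes Irf7 (-0.68) and Irf9 (-0.6) and Ifit3 (-1.83) were lower, in a list with 11 members lower adjusted over the list alone (camera adjusted p = 6.5e-08, adjusted p = 0.62 with an estimated correlation). The erythroid gene Trim10 was higher (1.7), as were Hbb-bs (1.05) and Alas2 (1.11), the 3 called of 19 erythroid genes (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.69 with an estimated correlation). The gene calls of Ly6a, Oasl2, Irf7, Irf9 and Ifit3 held without each library in turn, while that of Trim10 ended without SHI 2 (0.054) and those of Hbb-bs and Alas2 with each of the 6 libraries left out in turn (up to 0.11 and 0.15).

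JAK-STAT targets were lower in 2 of 21 (5 adjusted over the list alone, camera adjusted p = 0.0007, adjusted p = 0.62 with an estimated correlation), namely Socs3 (-0.26), a feedback inhibitor of cytokine signalling, and Bcl3 (-0.26). Immediate early genes were lower in 4 and higher in 1 of 26 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0071, adjusted p = 0.69 with an estimated correlation), with Dusp1 at -0.28 and Nr4a2 at 0.25. Adult-type genes were lower in 4 of 26 (5 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.62 with an estimated correlation). TGF-beta and BMP targets were lower in 4 of 20 (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.62 with an estimated correlation), with Id3 at -0.28. By fry, 0 of 28 lists passed, and 9 had an unadjusted camera p under 0.05. The TGF-beta call ended with gene ends only (0.63). Leaving out single libraries ended the erythroid call (SHI 3 or co-SHI 3, adjusted p up to 0.48), the immediate early call (SHI 3 or co-SHI 1, up to 0.062), the adult-type call (SHI 1, SHI 3, co-SHI 1 or co-SHI 2, up to 0.18) and the TGF-beta call (SHI 2, SHI 3, co-SHI 1 or co-SHI 2, up to 0.12). The lists called numbered 2 without SHI 3 and 3 without co-SHI 1. Kit (-0.12), Lin28b (0.15), Hmga2 (-0.1), Alb (-0.09), Igf2bp3 (0.03) and Ptprc (0.02) did not pass, and Peg3 (0.32, adjusted p = 0.015) was the member called of the fetal-type list. Without SHI 1, SHI 2, co-SHI 1 or co-SHI 2 the gene calls of Socs3, Dusp1, Nr4a2 and Id3 ended (adjusted p up to 0.15), and that of Bcl3 without any library but SHI 1 and co-SHI 3 (up to 0.17) and at thinned depth (0.069). Peg3 was lost without SHI 1, SHI 2 or co-SHI 2 (up to 0.085). With gene ends only Peg3 (0.28), Bcl3 (0.33) and Nr4a2 (0.092) lost their calls. Hmga2 (-0.16) and Lin28b (0.24) passed without co-SHI 3.

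**Figure D5:**
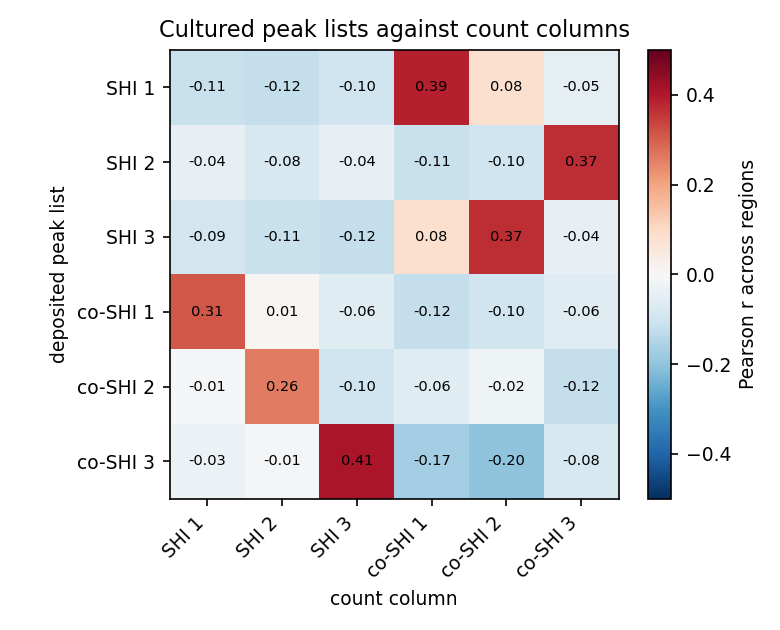
Pearson r across regions between each deposited peak list of the cultured cells (y axis) and each count column (x axis), printed in the cells. Every list has its highest r, between 0.26 and 0.41, in a column of the other group.

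The test called 813 of 145129 regions between the cultured groups, 331 higher and 482 lower in the libraries labelled co-SHI, with gene ends making up 23.6% of the higher and 8.3% of the lower against 12.6% of those tested. Counts summed per gene had the opposite balance, with 1213 of 17675 genes called, 793 higher and 420 lower. Regions called without single libraries were 104 higher and 442 lower without SHI 1, 58 and 192 without SHI 2, 238 and 243 without SHI 3, 45 and 140 without co-SHI 1, 35 and 178 without co-SHI 2 and 1354 and 2021 without co-SHI 3. The gene count was 463 with gene ends only (343 higher and 120 lower), 118 without SHI 1, 143 without SHI 2, 123 without co-SHI 1, 108 without co-SHI 2 and 3084 without co-SHI 3, with more genes higher than lower in each. A region at the end of Oasl2, an interferon-induced gene, stood at 4.52 ± 0.71 CPM in co-SHI and 13.6 ± 1.6 CPM in SHI (chr5:114897228-114898026, n = 3 each, log2 fold change -1.59, SE 0.19, adjusted p = 4.7e-06). A region in Agpat2, a gene of phospholipid synthesis, had a log2 fold change of -1.78 (chr2:26595592-26596557, SE 0.18, adjusted p = 4.5e-07) and an intergenic region near Tmprss2 of -1.26. Regions of Nsd2 (-5.14), Ppard (-3.48), Phlpp2 (-4.1), Plcz1 (-3.78), Dgkb (-4.3), Pacs1 (-3.73) and Myh15 (-4.58) were lower, with SDs among the SHI libraries from 6 to 11 CPM around means of 6.94 to 11.7 CPM. A region at the end of Trim10 was higher (chr17:36869186-36869688, 1.71), as were regions at Mup-ps16 (1.23), Klra5 (1.16), Rimbp2 (1.15), Prrx1 (1.13), Marchf1 (1.07), Nalcn (1.06), Pcdha12 (1.07), Atp2b4 (1.13) and Itpr1 (1.02). The calls at Prrx1, Marchf1, Nalcn, Pcdha12 and Itpr1 ended without co-SHI 2, and those at Nalcn, Pcdha12 and Itpr1 without co-SHI 1. Those at Nalcn and Itpr1 ended without SHI 3, those at Pcdha12 and Atp2b4 without SHI 1, and those at Atp2b4 and Itpr1 without SHI 2.

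The medium effect was set beside the change from E12.5 to E16.5 FL, since the medium was conditioned by E16.5 hepatocytes. Across 73822 regions found in both tables, the log2 fold changes of co-SHI over SHI and of E16.5 over E12.5 FL had r = -0.173 and rho = -0.168, where regions are not independent replicates and the sign is the opposite by the labels of the peak lists. No library was shared between these fits. The r was -0.207 over the regions of higher level and -0.085 without E12.5 FL 2. The Slc8a1 region, the call of the stage comparison, was not among the 565 medium calls of these regions.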

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

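The tests of exchanged names, of the co-varying regions and of the E12.5 PL libraries were all chosen only after the results were seen, though the thinned and loess-scaled counts they use were planned.

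The table of the cultured cells held 3 columns named as uncultured E12.5 FL libraries that no comparison used, with 16.1, 22.06 and 16.2 M counts against 3.97, 3.83 and 3.68 M in the columns of the same names in the developmental table. Across 73901 regions found in both tables, each correlated at r = -0.03 to 0 with the column of its name and at -0.02 to -0.01 with the peak list of its name.

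Cultured count columns and peak lists of the same name did not match. All 26 peak lists of the developmental series correlated best with their own column, which argues against a method that cannot tell libraries apart. All 6 cultured lists correlated best with a column of the other group, SHI 1 with co-SHI 1 (r = 0.39) and co-SHI 3 with SHI 3 (0.41) among them, a result that exchanged names in the count table or in the peak lists may explain. An exchange of the 2 group names alone would keep the replicate numbers, and the lists SHI 2 and SHI 3 matched co-SHI 3 and co-SHI 2 (0.37 each). Which of the sources holds the true names stays open, and with it the direction of every co-SHI against SHI difference, such as that of the interferon genes. No biological explanation was tested, since the names are a property of the deposit.

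A set of 65 regions moved together across the developmental libraries. They were called higher in 6w than in 4w BM and lower in 8w than in 6w BM, and regions of immediate early genes were left out. Its median log2 CPM differed by 3.85 between libraries of 1w BM, which argues against stage as the whole cause, and 56 of the 65 regions were still called for 8w against 6w BM after thinning, which argues against depth. In the 17 libraries not used to choose it, its first component held 85.4% of the variance, against at most 57.4% in 100 random sets of like level. One source of reads present in a different amount in each library is consistent with that value. What the source is stays open, and a biological state that varies between animals was not tested.

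The E12.5 PL libraries stood apart from all others. Depth is argued against by 44317 regions called after thinning, and reads concentrated at gene ends by the neutrophil, macrophage and lymphoid lists, called higher in E12.5 FL in all 6 tests with gene ends only or loess offsets. A smaller share of blood cells in E12.5 PL could raise endothelial, stromal and trophoblast genes alike. Their medians were -0.5, -0.16 and -0.14, and a permutation test of endothelial against stromal genes gave p = 0.076 (0.18 against trophoblast genes), so that such a share cannot be told apart from a difference within blood cells. Purity was not measured, and a difference between the sites themselves stays open and untested.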

How the results depend on the processing

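The counts outside the co-varying regions, the any-group count without E12.5 PL, the gene-end setting and the tests of the cultured gene count were chosen after seeing the data, and the other tests were planned. Of 150 alternative values of the main comparisons, leaving single libraries out aside, 121 stayed within 1.5 times the reported count or within the spread and 29 did not. With total counts the balance of directions turned, from 65.3% to 43% of calls higher for 8w BM against E12.5 FL and from 46.7% to 63.2% for E12.5 FL against E12.5 PL. The cause was not tested except where stated.

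With loess offsets the calls numbered 31970 for E12.5 FL against E12.5 PL and 1778 for perinatal BM against E16.5 FL, and total counts gave 4773 for the latter. DESeq2 called 33 regions for E16.5 against E12.5 FL, 90 for 1w against perinatal BM, 185 for 3w against 1w BM, 0 for 4w against 3w BM and 44 for 8w against 6w BM. Fits of the compared groups alone called 2, 5067, 101 and 434 for E16.5 against E12.5 FL, perinatal BM against E16.5 FL, 4w against 3w BM and 6w against 4w BM. Thinning gave 15 for 4w against 3w BM. Outside the co-varying regions 97, 1, 102 and 19 regions were called for 1w against perinatal, 4w against 3w, 6w against 4w and 8w against 6w BM, and since the set was chosen from calls of the last 2, the drop there is partly by construction. Over any group 27584 regions were called without E12.5 PL. The medium correlation was -0.207 above the median level.

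Of 28 lists, gene ends alone gave 1 call for E16.5 against E12.5 FL, 3 for perinatal BM against E16.5 FL and 2 for 1w against perinatal BM. Loess offsets gave 0 for perinatal BM against E16.5 FL, where with TMM 9 had an unadjusted camera p under 0.05 and fry called 10 lists, 2 for 4w against 3w BM and 6 for 8w BM against E12.5 FL.

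Replicate numbers do not pair the samples, since deviations of libraries with the same number correlated at r = -0.1 to 0.15 and not above 0.1 in every pair of any comparison. The replicate block gave 19 regions for 4w against 3w BM, and 1 list each for 3w against 1w and 4w against 3w BM. Of 47 named gene calls of co-SHI against SHI the block ended 6, and Igf2bp3 passed with it for 3w against 1w and 6w against 4w BM.

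Leaving out single libraries gave, as lowest and highest counts in the order of development, 39539 and 44038, 0 and 22, 2791 and 6958, 18 and 230, 13 and 86, 0 and 4, 91 and 173, and 34 and 115 regions. It gave 9605 and 15504 for 8w BM against E12.5 FL, 185 and 3375 for co-SHI against SHI, 108 and 3084 genes for co-SHI against SHI, 58158 and 63543 over any group, and a medium correlation of -0.193 to -0.085. The lists called ranged, in the same order, over 12 to 13, 0 to 5, 5 to 8, 3 to 7, 1 to 3, 0 to 3, 2 to 5, 1 to 3, 10 to 14 and 2 to 6. The ratios of peak numbers ranged over 0.67 to 0.82, 0.56 to 0.74, 1.83 to 2.49, 1.25 to 1.67, 0.95 to 1.2, 0.68 to 0.91, 0.9 to 1.19, 0.96 to 1.23, 1.63 to 2.1 and 0.68 to 0.9.

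For the 134 named results, each a region in a comparison, 1720 of 1839 values kept their direction and side of the threshold, 119 lost the call, 0 reversed, and 98 of the results never lost it. For the 339 gene calls under the rule for named genes, 4296 of 4971 values kept direction and call, 661 lost the call, 14 reversed and 164 of the calls were never lost. All 14 reversals came with gene ends only, where fewer regions stand for a gene and 463 genes were called for co-SHI against SHI. They were Bnip3 (0.19), Cdkn1a (0.26), Dlk1 (-0.01), Eng (0.91), Hoxb1 (0.8), Kit (0.2) and Sox17 (0.22) for E12.5 FL against E12.5 PL, Ptprc (-0.01) for perinatal BM against E16.5 FL, Cd9 (-0.38), Csf1r (-0.29), Siglech (-0.6) and Ywhaz (-0.35) for 8w BM against E12.5 FL, and Smad7 (0.01) and Tcf7 (0.1) for co-SHI against SHI. A lone 3w BM library was assumed to vary like the other groups. Offsets for GC content, the motif test and distances to transcription starts were not run, since no genome sequence or strand was used. Thinning gave 1 call for E16.5 against E12.5 FL, 185 for 1w against perinatal BM and 74 for 3w against 1w BM. Full depth gave 1, 179 and 88.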

Other observations

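Camera called neither the homing nor the hepatocyte list between stages, although single members passed. Fry called the homing list higher in perinatal BM than in E16.5 FL (adjusted p = 0.03) and in E12.5 FL than in E12.5 PL (0.0025). Cxcr4, the receptor that holds progenitors in the marrow, rose between E16.5 FL and perinatal BM (log2 fold change 0.48, SE 0.1, edgeR adjusted p = 0.0012), as did the egress receptor S1pr1 (0.41) and the integrin Itga4 (0.35), with 5 higher and 1 lower of 22 homing genes (also adjusted over the list alone, camera adjusted p = 0.21). Loess offsets ended the calls of S1pr1 (0.24) and Itga4 (0.2), gene ends only those of Cxcr4 (0.29) and Itga4 (0.23), and leaving out perinatal BM 2 those of S1pr1 and Itga4. Itga4 was also lost with total counts and without E16.5 FL 1 or perinatal BM 1. Between E12.5 FL and 8w BM 3 of 22 rose and 6 fell (also adjusted over the list alone, camera adjusted p = 0.8), with Cxcr4 1.6-fold higher and Cdh2 (-0.63), Itgb1 (-0.43) and Cxcl12 (-0.72) lower. At E12.5, Itga4 (1.54) and Itgal (1.79) were higher in E12.5 FL than in E12.5 PL, and Itga6, a laminin-binding integrin subunit, was lower (-0.76). Among hepatocyte genes, Alb (-1.02) and Ttr (-1.3) fell between E12.5 FL and 8w BM, while Apoa2 (0.58) and Ahsg (1.01) rose. The Ttr call ended with loess offsets (-0.9), that of Itgb1 with gene ends only (-0.2), and that of Ahsg without E12.5 FL 1 or 3 or 8w BM 1 or 2 (adjusted p up to 0.13).

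The tests of other splits were planned, except that of the cultured gene count, which like the look at co-varying regions of the cultured cells was chosen only after the result was seen. Over the 76 regions called lower by at least 4-fold in the libraries labelled co-SHI, the median log2 CPM was 0.82, 1.64 and 3.47 in the SHI libraries and -0.84, -0.67 and -1.29 in the co-SHI libraries, groups that differ there by the choice of the regions. In the 3 columns named as uncultured E12.5 FL it was 1.9, 1.39 and 3.8. With the mean of these regions 676 regions correlated at r above 0.85, of which 83 were called, and 730 of the 813 calls lay outside them.

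Libraries were divided into other groups of the same sizes and the compared groups fitted alone. The 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 43554 and 0 regions for E12.5 FL against E12.5 PL, 2 and 6 for E16.5 against E12.5 FL, 5067 and 3 for perinatal BM against E16.5 FL and 199 and 16 for 1w against perinatal BM. They gave 434 and 140 for 6w against 4w BM, 135 and 151 for 8w against 6w BM, 16880 and 0 for 8w BM against E12.5 FL, and 813 and 62 for co-SHI against SHI. For genes of co-SHI against SHI they gave 1213 and 0, with 1 of 10 splits as large. As many regions as in the real split came from 1, 2, 1, 1, 1, 2, 1 and 1 of the 10. The medium correlation was -0.173, and the highest other in size -0.129, with 1 of 10 splits as large. Over any group, E12.5 PL included, the real split gave 63716 regions and the highest other 5310. Of 40 drawn splits 1 was as large, the fewest possible.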
